A study of Bos taurus with 6 samples.

How the data were processed

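RNA was measured in 6 libraries of bovine mammary epithelial cells, 3 control and 3 with acetate and BHBA added. Per the labels' protocols, RNA had an integrity number above 8, poly(A) RNA was selected with oligo(dT) beads, libraries were made with a TruSeq RNA kit and amplified by PCR, and paired-end reads were taken on an Illumina HiSeq instrument. The authors deposited 1 table of FPKM values for 24616 genes with Ensembl gene identifiers, 1 column per library, rounded to 2 decimals. The unit comes from the name of that deposited table and fits its values, which are never negative and sum to between 787186 and 1134026 per library. Per the submitters' processing notes, the genome build was ARS-UCD1.2, and the notes name DESeq2 with no role. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The number of gene identifiers resembles that of an older Ensembl annotation made on an earlier build. Which gene models, and so which gene lengths, lie behind the FPKM values therefore stays unsettled. Antisense, overlapping and near-identical genes are therefore uncertain where reads could be shared between them.

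FPKM divides fragments by gene length and by the number of fragments mapped, so it keeps no read counts. The smallest value above 0 was 0.01 in each library, the rounding step itself, so that reads could not be recovered from the steps between low values, and the depth of each library is unknown. No count model was fitted, and no interval that needs depth is given. Replicate spread is the only error available, and with 3 libraries per group and 4 residual degrees of freedom it is itself imprecise.

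Each column was assigned to a sample by its name, and each sample to a group by its title. The names of the treated columns give acetate and the replicate number but not BHBA, and were matched to the treated samples, the only ones whose titles name acetate. Gene symbols came from the table for 18535 genes, from RefSeq protein accessions in the table for 124 (matched to NCBI gene records of assembly ARS-UCD2.0, used for names only) and from the table's descriptions for 21. The other 5936 kept an identifier only. No coordinates are given, because no annotation of the labels' build was used. All calculations were made with R 4.3.3 and limma 3.58.1, and tables and plots with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

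Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11615 in all. Values were taken as log2(FPKM + 0.5) with no further scaling, and treated and control libraries were compared with limma's moderated test, with a mean-variance trend, 2-sided, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. A further count required an absolute log2 fold change of at least 1. Standard errors are the moderated ones. No covariate or block was used.

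Before the data were examined, 35 gene lists were written, with 654 distinct members, of which 600 were found, 9 of them through an older symbol. They covered milk fat, milk protein, cholesterol, ketone and energy metabolism, stress and signalling responses, cell growth and markers of mammary and other cell types. Lists with at least 5 tested members (32) were tested with limma camera at an inter-gene correlation of 0.01, adjusted over those lists, and again with the correlation estimated for each list and with fry. camera compares a list with all other genes, and fry asks whether a list's genes move, on balance, one way. Members were also counted with adjustment over the list alone.

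The genes named in the text were fixed by a rule before the data were examined. Among genes past the threshold with a symbol, at least 5 FPKM in the higher group and no overlap between the groups, the rule took the 10 largest rises and the 10 largest falls. Where fewer passed, it took all of them and then the genes with the smallest p up to 10. It also took up to 4 members with the smallest p in the direction of each list that passed, up to 3 of the other lists described, and a fixed milk fat panel of ACACA, FASN, SCD, ACSS2, ACLY, CD36, LPL, FABP3, SREBF1, PPARG, INSIG1, GPAM, DGAT1, LPIN1, PLIN2, XDH, BTN1A1, BDH1, OXCT1, CSN2 and CSN3. Genes named outside the rule were chosen after their values were seen. They are KRT7, KRT18, RPL27, CSN1S1, CSN1S2, PAEP, GLYCAM1, LALBA, PRLR, MKI67, COL1A1, COL1A2, BNIP3, PER1, H1F0, SYNGR3 and bta-mir-2904-3. AHNAK and DST stand only as examples of long mRNAs.

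The alternatives were a pseudocount of 0.1 or 1, no filter on low values or a mean of at least 5 FPKM, quantile normalization, rescaling to the same sum in each library, trimmed-mean factors computed from FPKM, a variance estimate with no trend or a robust one, the replicate number as a block, and leaving out each library in turn with the filter applied to those left. After the data were seen, the log2 of each library's summed FPKM was added as a covariate. Sample weights were also tried after the data were seen and are not reported, because their estimate did not settle.

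The steps were tested on simulated data for this comparison, drawn for the 11615 genes from their means and variances, with 200 genes changed and 20 runs. With independent noise, the main test recovered 31.3% of 2-fold and 71.8% of 4-fold changes, and 4.69% of its calls were false, while the fit with the covariate recovered 5.17% and 32.6%, with 3.07% false. With the main axis of the real libraries kept in the noise, the main test recovered 19.2% and 70.1%, with 0.460% false. The fit with the covariate then recovered 83.2% and 97.6%, with 4.41% false. That axis was taken from deviations within groups, and the rest of the noise was drawn independently for each gene. The 4.41% therefore does not measure false calls of the covariate fit in the real libraries. A list of 20 genes shifted by 0.5 was called by camera in 20 of 20 runs in both kinds of noise, and of 620 unchanged lists 0 were called. The unchanged lists were random draws of genes, whereas members of a real list can move together. The 0 of 620 therefore does not measure false calls for the real lists.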

Results

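The data came from cultured bovine (Bos taurus) mammary epithelial cells, the cell type that makes and secretes milk. Cells to which acetate and BHBA had been added were set against control cells, with 3 RNA-seq libraries in each group. The titles of the treated samples give the acetate as NaAc, its sodium salt. The labels name no control with matched sodium, so effects of sodium cannot be told apart from those of acetate and BHBA. Acetate is the main carbon source of the fatty acids made in the ruminant mammary gland, and BHBA (beta-hydroxybutyrate) is a ketone body that the gland also uses. The series describes the treated cells as a model of high milk fat, so the comparison asked which genes differ between cells with and without the 2 substrates. The doses and the length of the treatment are not given in the sources used here. Values were FPKM (fragments mapped to a gene, scaled by its length and by all fragments mapped) for 24616 genes, 1 column per library. FPKM summed to 1134026 in control replicate 1, 847971 and 816087 in control replicates 2 and 3, and 787186, 936152 and 912431 in treated replicates 1, 2 and 3. FPKM values hold no read counts, so the depth behind each value is unknown. Nothing in the labels says that the libraries came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

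The cells carried epithelial transcripts at high levels in both groups. KRT5, a keratin of basal epithelium, stood at 9104 ± 243 FPKM in control cells and 6380 ± 409 in treated cells (SD, n = 3 per group; log2 fold change -0.51 ± 0.20 SE, adjusted p = 0.418). KRT7 and KRT18, keratins of luminal epithelium, had control means of 3243 and 1298 FPKM. Of the milk proteins, CSN3 (kappa-casein) was present at 17.3 ± 1.72 FPKM in control and 16.2 ± 2.83 in treated cells (log2 fold change -0.11 ± 0.17, adjusted p = 0.921). Without treated replicate 1 its log2 fold change was 0.04. CSN2 (beta-casein) was listed at 0 in all 6 libraries. So were the milk protein genes CSN1S1, CSN1S2, PAEP and GLYCAM1, while LALBA reached at most 0.1 FPKM in any library. PRLR, the prolactin receptor, reached at most 0.04 FPKM. Of the 18 members found of the milk protein and lactogenic list, 8 lay below the minimum of 1 FPKM. RPL27, a ribosomal protein gene, was also listed at 0 in all 6, so a 0 in these values need not mean an absent transcript.

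Between cells with and without acetate and BHBA, 55 of the 11615 genes tested differed, of which 40 rose and 15 fell (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Fold changes are on the scale of log2(FPKM + 0.5), which understates the change of low genes. The largest rise among genes chosen by the naming rule was that of EEF1A2 (ENSBTAG00000021685), a translation elongation factor best known from muscle and neurons, from 0.887 ± 0.0862 to 14.9 ± 3.61 FPKM (SD; log2 fold change 3.45 ± 0.21 SE, 10.9-fold, adjusted p = 0.0107). CRNN (cornulin, ENSBTAG00000019540), a marker of squamous epithelial differentiation, rose from 38.9 ± 7.62 to 320 ± 53.3 FPKM (log2 fold change 3.03 ± 0.20, adjusted p = 0.0107). CITED1 (ENSBTAG00000045925), a transcriptional co-regulator, fell from 20.7 ± 7.66 to 1.70 ± 0.50 FPKM (log2 fold change -3.24 ± 0.30, adjusted p = 0.0220). DHRS3 (ENSBTAG00000024493), a reductase that turns retinaldehyde into retinol, fell from 362 ± 58.8 to 55.4 ± 8.43 FPKM (log2 fold change -2.69 ± 0.18, adjusted p = 0.0107).

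Other genes that rose were MMP23B, a metalloproteinase (log2 fold change 2.73 ± 0.20), NAP1L5 (2.28 ± 0.21), the secreted Wnt antagonist DKK1 (2.28 ± 0.25) and SLC6A12, which carries the osmolyte betaine (2.23 ± 0.25). SCNN1A, a subunit of the epithelial sodium channel, rose by 2.14 ± 0.15, ACHE (acetylcholinesterase) by 2.13 ± 0.15, PIANP by 2.07 ± 0.20 and TSC22D3, a gene known to be induced by glucocorticoids, by 2.04 ± 0.26 on the log2 scale. Their adjusted p-values lay between 0.0107 (MMP23B, SCNN1A and ACHE) and 0.0437 (TSC22D3). Of 17 alternatives, MMP23B, SCNN1A and ACHE passed in 11, DKK1 and SLC6A12 in 10 and TSC22D3 in only 5. NAP1L5 and PIANP passed in 9 of 16. TSC22D3 did not pass with quantile normalization, rescaling, trimmed-mean factors or the robust variance estimate. Among falls, BoLA DR-ALPHA, a chain of the class II antigen-presenting complex, had a log2 fold change of -1.33 ± 0.16, KLHL32 of -1.18 ± 0.16 and IGFBP5, an insulin-like growth factor binding protein, of -1.10 ± 0.14. DCXR (-1.07 ± 0.13) and NQO1, a quinone reductase (-1.02 ± 0.13), completed the 7 falls that met the naming rule. Adjusted p-values ran from 0.0107 (DHRS3) to 0.0471 (KLHL32) over all 7. Of 17 alternatives, CITED1 and DHRS3 passed in 11, BoLA DR-ALPHA in 10, NQO1 in 9, DCXR in 8, KLHL32 in 7 and IGFBP5 in 5. The next 3 genes by p did not pass: BATF2 stood at -1.27 ± 0.17 (adjusted p = 0.0512), SLC7A8 at -1.34 ± 0.19 (adjusted p = 0.0562) and KCNMB1 at -1.02 ± 0.15 (adjusted p = 0.0565).

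**Figure D1:**
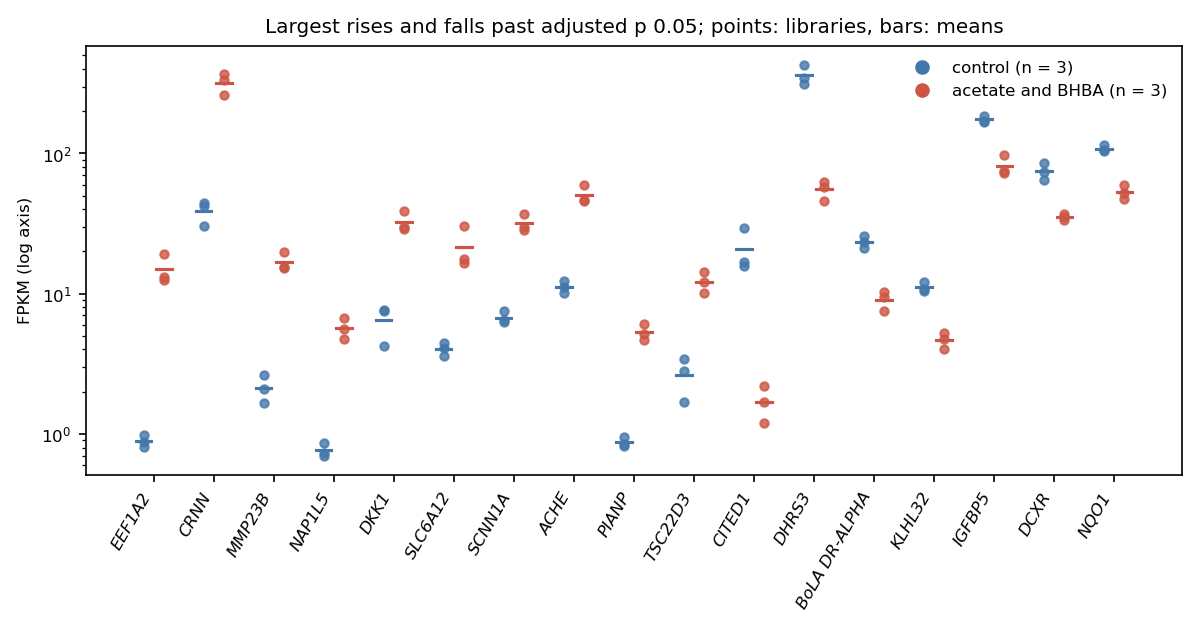
FPKM on a log axis for the 10 genes with the largest rises and the 7 with the largest falls that met the naming rule; points are libraries (3 control in blue, 3 treated in red) and bars are group means. In each gene the 3 libraries of one group lie above the 3 of the other, as for CRNN with means of 38.9 and 320 FPKM.

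At least 2-fold changes were found in 50 of the 55 genes, 36 higher and 14 lower. At an unadjusted p under 0.05 there were 862 genes higher and 420 lower. The groups did not overlap in any of the 55 called genes, nor in 2283 of all genes tested (19.7%, where chance gives 10%). With quantile normalization 62 genes passed, 35 higher and 27 lower, so that 56.5% of calls were higher in place of 72.7%. After rescaling to a fixed sum 23 passed (16 higher and 7 lower), with a mean of at least 5 FPKM 33, and with the summed FPKM as a covariate, added after the data were seen, 2089 (1361 higher and 728 lower). The number of calls changed when a library was left out. It was 205 without control replicate 1, 0 without control replicate 2 and 1 without control replicate 3. Without treated replicate 1, 2 or 3 it was 0. In the fits with 0 calls, limma gave 731 to 921 genes at an unadjusted p under 0.05. These fits have 1 library fewer and so fewer residual degrees of freedom. The lost calls therefore do not show that any single library carried them. Of the 110 tested genes that the naming rule took and that did not pass, 28 had a log2 fold change moved by over 1.5 times and 5 turned in sign without control replicate 1, where 13 passed.

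Genes of fatty acid synthesis stood higher in treated cells, with 15 of 16 measured members on that side. In that list, 2 members rose: FADS2, the delta-6 desaturase, from 37.3 ± 4.44 to 100 ± 4.38 FPKM (log2 fold change 1.42 ± 0.13, adjusted p = 0.0220), and ACSS2, which activates acetate to acetyl-CoA, from 33.0 ± 3.72 to 73.2 ± 5.88 FPKM (1.14 ± 0.13, adjusted p = 0.0346). The other 14 did not pass, and the count adjusted over the list alone was also 2. ACLY, the citrate lyase, had a log2 fold change of 1.14 ± 0.36 (adjusted p = 0.305), SCD, the delta-9 desaturase, of 0.96 ± 0.36 (adjusted p = 0.381) and FADS1 of 0.84 ± 0.27 (adjusted p = 0.311). ACACA, the rate-limiting carboxylase, stood at 0.00 ± 0.17 (adjusted p = 0.999) and FASN, the fatty acid synthase, at 0.20 ± 0.21 (adjusted p = 0.865). Without control replicate 1, ACLY had a log2 fold change of 0.73, SCD of 0.59, ACACA of 0.12 and FASN of -0.01. The list as a set was shifted higher (limma camera, adjusted p = 0.000275), with an adjusted p = 0.284 with an estimated correlation, the highest of a range from 1.50e-05 over 19 alternatives.

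Fatty acid uptake, binding and activation genes were also shifted higher as a set (camera adjusted p = 0.0493, but adjusted p = 0.236 with an estimated correlation), with 0 of 11 members past the threshold and 3 adjusted over the list alone. FABP3, the fatty acid binding protein abundant in lactating gland, stood at 10.3 ± 3.47 FPKM in control and 24.3 ± 1.80 in treated cells (log2 fold change 1.23 ± 0.23, adjusted p = 0.0980). SLC27A3 had a log2 fold change of 1.06 ± 0.26, FABP5 of 0.51 ± 0.13 and ACSL1 of 0.88 ± 0.30 (0.54 without control replicate 1), none past the threshold. SLC27A3 was low, with means of 1.29 FPKM in control and 3.31 in treated cells. The set call was lost in 8 of 19 alternatives, among them those without control replicate 2, control replicate 3 or treated replicate 3 (adjusted p = 0.0656, 0.0913 and 0.0903), with 0.00899 as the lowest value and that with an estimated correlation as the highest. CD36 and LPL, a fatty acid transporter and a lipase, were close to 0 in both groups, with at most 0.040 FPKM as a group mean. BTN1A1, a coat protein of the milk fat globule, was listed at 0 in all 6 libraries.

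Lipid transcription regulators were shifted higher (13 of 15 on that side, camera adjusted p = 0.000173). The call was lost with adjusted p = 0.236 with an estimated correlation, the highest of a range from 7.58e-05. INSIG1, a sterol-regulated inhibitor of SREBP processing, rose from 58.5 ± 5.35 to 129 ± 6.57 FPKM (log2 fold change 1.14 ± 0.12, adjusted p = 0.0315). It was the 1 member past the threshold, against 4 adjusted over the list alone, which added SREBF1 (0.49 ± 0.10), PPARA (0.62 ± 0.14) and MLX (0.47 ± 0.11). PPARG stood at 0.39 ± 0.22 (adjusted p = 0.628), or 0.18 without control replicate 1.

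Cholesterol synthesis and uptake genes were all on the higher side in treated cells, 22 of 22, or 21 with quantile normalization, trimmed-mean factors or the summed FPKM as a covariate (camera adjusted p = 7.52e-10). This call too was lost, with adjusted p = 0.236 with an estimated correlation, the highest of a range from 4.41e-11. INSIG1, which this list shares, was the 1 member that rose among all genes tested, while 10 members passed adjusted over the list alone. DHCR7, a late enzyme of cholesterol synthesis, stood at 127 ± 9.46 FPKM in control and 219 ± 9.53 in treated cells (log2 fold change 0.79 ± 0.11, adjusted p = 0.0562). ACAT2 had a log2 fold change of 0.72 ± 0.15 (adjusted p = 0.117) and MSMO1 of 0.53 ± 0.11 (adjusted p = 0.125). Cholesterol efflux and LXR target genes were shifted higher (5 of 6 on that side, 0 past the threshold, 1 adjusted over the list alone, camera adjusted p = 0.0200). That call was lost without a filter on low values (adjusted p = 0.0632) and with an estimated correlation (adjusted p = 0.236), over a range from 0.00998. ABCA7, the 1 that passed over its list, had a log2 fold change of 1.21 ± 0.24, APOE of 1.18 ± 0.39, NR1H3 (the LXR alpha receptor) of 0.59 ± 0.26 and LPCAT3 of 0.25 ± 0.13 (0.15 without treated replicate 2).

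Ketone body and acetate genes were shifted higher (10 of 11 on that side, or 8 with quantile normalization or trimmed-mean factors, camera adjusted p = 0.0107). The call was lost with an estimated correlation (adjusted p = 0.236, the highest of a range from 0.00160). It was also lost without control replicate 3 (adjusted p = 0.0622) or treated replicate 3 (adjusted p = 0.0537), and without a filter on low values (adjusted p = 0.0853). ACSS2, shared with the fatty acid list, was the 1 member that rose, and 3 passed adjusted over the list alone. ACAT1, the mitochondrial thiolase, had a log2 fold change of 0.44 ± 0.11, AACS, which activates acetoacetate, of 0.52 ± 0.13, BDH1, the BHBA dehydrogenase, of 0.43 ± 0.17 and OXCT1, which brings ketone bodies into oxidation, of 0.41 ± 0.20. Without control replicate 1, BDH1 stood at 0.27 and OXCT1 at 0.25.

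**Figure D2:**
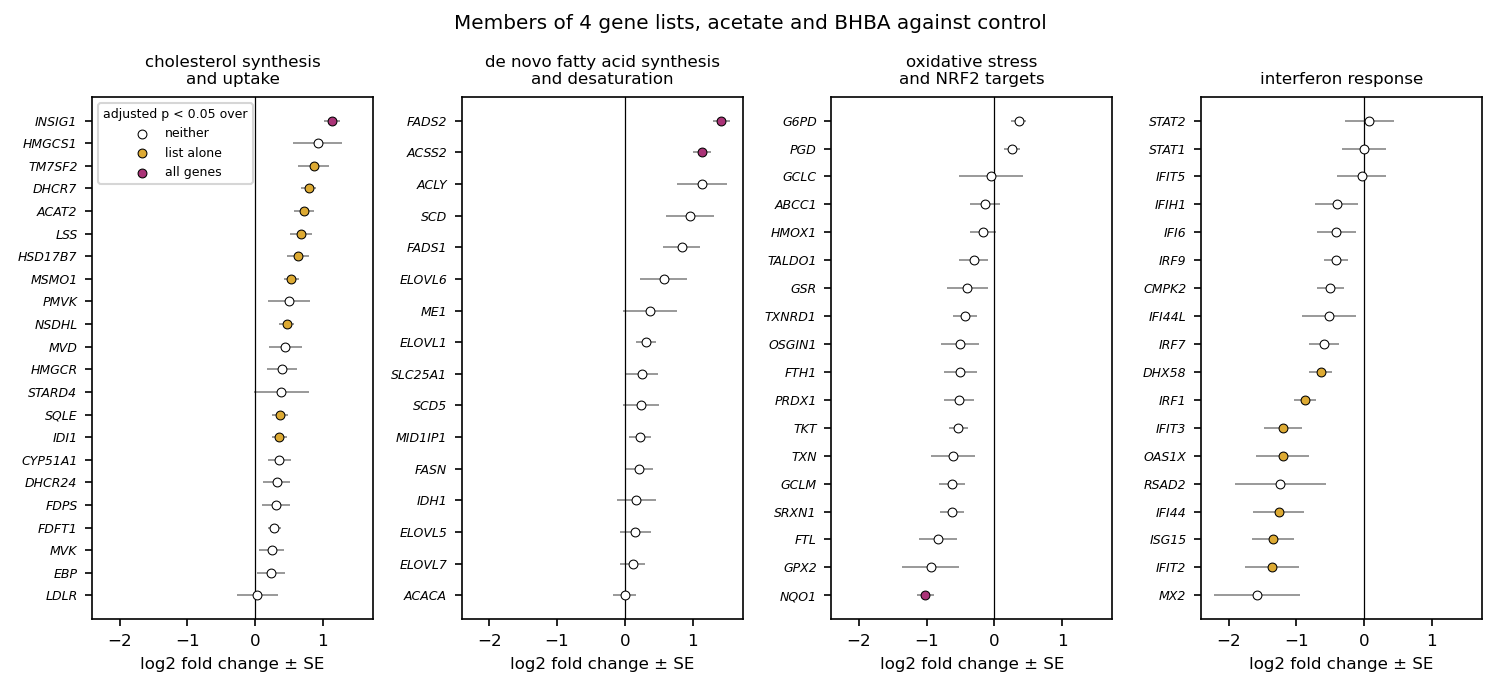
log2 fold change of each tested member, treated against control, with bars of 1 SE, for 4 gene lists; fill shows whether the member passed among all genes tested, over its list alone, or neither. All 22 members of the cholesterol list lie above 0 (21 with quantile normalization, trimmed-mean factors or the summed FPKM as a covariate), while 16 of 18 members of the oxidative stress list and 17 of 18 of the interferon list lie below it.

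Interferon response genes were shifted lower (17 of 18 on that side, camera adjusted p = 2.13e-10), with 0 past the threshold among all genes tested and 7 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.236, the highest of a range from 4.60e-13). ISG15, a ubiquitin-like protein induced by interferon, stood at 110 ± 37.3 FPKM in control and 42.4 ± 11.3 in treated cells (log2 fold change -1.35 ± 0.31, adjusted p = 0.154). IRF1 had a log2 fold change of -0.87 ± 0.16 and DHX58 of -0.64 ± 0.17. IFIT3, at -1.20 ± 0.28, was low in both groups, with means of 2.06 FPKM in control and 0.617 in treated cells. On the lower side were 15 members after rescaling to a fixed sum and all 18 with quantile normalization, trimmed-mean factors or the covariate. Of the inflammation and NF-kB targets, IL6 rose from 82.6 ± 4.16 to 206 ± 25.9 FPKM (log2 fold change 1.31 ± 0.13, adjusted p = 0.0249), while the chemokines CCL5 (-1.99 ± 0.39, adjusted p = 0.109) and CCL2 (-0.59 ± 0.14, adjusted p = 0.184) were lower without passing. Adjusted over the list alone, IL6 rose and those 2 fell, and the list as a set did not pass (7 higher and 11 lower of 18, or 9 and 9 after rescaling, adjusted p = 0.319). It passed only without treated replicate 3 (adjusted p = 0.0358, the lowest of a range to 0.989).

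Oxidative stress and NRF2 target genes were shifted lower (16 of 18 on that side, camera adjusted p = 5.74e-07). With an estimated correlation the set did not pass (adjusted p = 0.236, the highest of a range from 2.24e-09). NQO1 fell from 108 ± 5.66 to 53.1 ± 6.06 FPKM (adjusted p = 0.0413) and was the 1 member past the threshold, also adjusted over the list alone. TKT, a pentose phosphate enzyme, stood at 1294 ± 70.03 FPKM in control and 895 ± 47.0 in treated cells (log2 fold change -0.53 ± 0.14, adjusted p = 0.197), SRXN1 had a log2 fold change of -0.63 ± 0.17 and GCLM of -0.62 ± 0.19. Cell cycle genes were shifted lower by small amounts (26 of 31 on that side, median log2 fold change -0.27, camera adjusted p = 7.58e-08), with 0 members past the threshold either way, and 0 adjusted over the list alone. For the cell cycle set, adjusted p = 0.236 with an estimated correlation, the highest of a range from 9.31e-11, and fry gave 0.111. PLK1 stood at -0.44 ± 0.11, BIRC5 at -0.32 ± 0.10, RRM2 at -0.55 ± 0.20 and UBE2C at -0.49 ± 0.19 (-0.31 without control replicate 1), while the proliferation marker MKI67, chosen after its value was seen, stood at 0.03. Without control replicate 1 MKI67 stood at -0.49, and without treated replicate 1 at -0.25. Without any other single library it was higher, between 0.15 and 0.28.

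Immediate early genes were shifted higher (14 of 17 on that side, 0 past the threshold, 1 adjusted over the list alone, camera adjusted p = 0.0435). The call was lost in 6 of 19 alternatives. It gave an adjusted p = 0.755 with an estimated correlation, the highest of a range from 0.00606. The other losses were with fry (adjusted p = 0.282), after rescaling (0.151), with the summed FPKM as a covariate (0.104), and without control replicate 1 (0.338) or treated replicate 1 (0.109). NR4A1 had a log2 fold change of 1.10 ± 0.21, KLF4 of 0.50 ± 0.15, FOS of 0.89 ± 0.28 and DUSP1 of 0.67 ± 0.24 (0.43 without control replicate 1). Fibroblast markers were shifted higher too (11 of 14 on that side, 0 past the threshold, 3 adjusted over the list alone, camera adjusted p = 0.0137). This call was lost in 4 of 19 alternatives. It gave an adjusted p = 0.236 with an estimated correlation, the highest of a range from 0.00825. The other losses were without control replicate 1 (adjusted p = 0.160), with the summed FPKM as a covariate (0.160) and with quantile normalization (0.0531). THY1 stood at 4.31 ± 1.94 FPKM in control and 16.8 ± 2.40 in treated cells (log2 fold change 1.91 ± 0.31, adjusted p = 0.0711), S100A4 had a log2 fold change of 1.36 ± 0.26, MMP2 of 0.54 ± 0.13 and DCN of 0.76 ± 0.24. Of the collagens in the same list, COL1A1 stood at 0.19 and COL1A2 at -0.09, or at -0.08 and -0.42 without control replicate 1, both chosen after their values were seen. They stood at 0.32 and 0.10 without control replicate 2, and at 0.35 and 0.05 without control replicate 3. Beside them, TGF-beta and matrix genes did not pass as a set (15 of 20 higher, adjusted p = 0.128, 0 past the threshold), with COL5A1 at 0.94 ± 0.16, CTGF at 0.78 ± 0.15 and TGFBI at -0.88 ± 0.17. Adjusted over the list alone, 3 of them rose and 1 fell. That set passed without treated replicate 2 (adjusted p = 0.0412) and with a mean of at least 5 FPKM (0.0199, the lowest of a range to 0.755).

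Most adipocyte, endothelial and immune markers lay below the minimum of 1 FPKM. Of the adipocyte markers 3 of 9 reached it (LIPE, CFD and PPARG, the last at 8.47 FPKM in treated cells). CFD stood at 0.943 ± 1.11 FPKM in control cells (2.23 in replicate 1) and 2.69 ± 0.43 in treated cells (log2 fold change 1.40 ± 0.51, adjusted p = 0.375). Without control replicate 1 it passed, at 1.99 (adjusted p = 0.0244), and with the covariate at 1.64 (adjusted p = 0.00589, the lowest of a range to 0.999). Of the endothelial markers 1 of 9 did (VWF, 4.77 FPKM in treated cells, log2 fold change 0.55 ± 0.23), and of the immune markers 1 of 12 (CD14, 7.09 FPKM in treated cells, 0.65 ± 0.18, adjusted p = 0.237), too few for a set test. No member of these 3 lists passed among all genes tested, and CD14 passed adjusted over its list alone, as the single gene in it, and among all genes with the covariate (adjusted p = 0.0189, the lowest of a range to 0.986). Luminal markers (11 of 14 lower, adjusted p = 0.128), basal markers (9 of 14 higher, adjusted p = 0.662) and keratinocyte differentiation genes (4 of 7 higher, adjusted p = 0.842) did not pass, with 0 members past the threshold, or adjusted over the list alone, in each. These sides depended on the scaling. After rescaling or with the covariate 7 luminal markers were lower, and with quantile normalization 8. With the covariate 7 basal markers were higher, and 3 keratinocyte genes were higher with quantile normalization, trimmed-mean factors or the covariate. Their members with small p included ELF3 (-0.39 ± 0.18, or -0.25 without control replicate 1), KRT15 (-0.60 ± 0.22) and TGM1 (0.66 ± 0.24).

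The remaining milk-related and metabolic lists did not pass as sets with camera. By fry, which does not compare a list with other genes, 2 of them were called higher, triacylglycerol synthesis and lipid droplet genes (adjusted p = 0.0319, the lowest of a range to 0.939) and milk fat globule secretion genes (adjusted p = 0.0156, the lowest of a range to 0.592). Triacylglycerol synthesis and lipid droplet genes had 0 of 19 members past the threshold, and 0 adjusted over the list alone (camera adjusted p = 0.647), with LPIN1 at 0.93 ± 0.32 (adjusted p = 0.341), GPAM at 0.35 ± 0.31, DGAT1 at 0.16 ± 0.16 and PLIN2, the lipid droplet coat protein, at -0.02 ± 0.14. Without control replicate 1, LPIN1 stood at 0.60, GPAM at 0.08 and XDH at 0.43. Without control replicate 3, DGAT1 stood at 0.05, and PLIN2 was above 0 without control replicate 3 (0.07) or treated replicate 3 (0.04). Milk fat globule secretion genes had 0 of 6 (camera adjusted p = 0.319), with XDH at 0.71 ± 0.25 (adjusted p = 0.350), and FABP3 passed adjusted over the list alone. Lipolysis genes had 0 of 7, and 0 adjusted over the list alone (adjusted p = 0.893, LIPE at 0.32 ± 0.24). Beta-oxidation and PPAR targets had 0 of 25 (adjusted p = 0.583), and ANGPTL4 at -0.97 ± 0.17 passed adjusted over the list alone, as did CISH at -0.77 ± 0.15 of the milk protein and lactogenic list (0 of 10, adjusted p = 0.319). Of the glycolysis genes PFKM, the muscle-type phosphofructokinase, rose from 3.72 ± 0.253 to 8.76 ± 0.572 FPKM (log2 fold change 1.13 ± 0.15, adjusted p = 0.0444). PFKM passed in 6 of 17 alternatives. ALDOC stood at 1.09 ± 0.21, and 2 glycolysis genes passed adjusted over the list alone (set adjusted p = 0.556). Tricarboxylic acid cycle genes (0 of 21, adjusted p = 0.319, OGDH at 0.27 ± 0.11), oxidative phosphorylation genes (0 of 35, adjusted p = 0.319, UQCRC2 at 0.13 ± 0.11) and ribosomal protein genes (0 of 24, adjusted p = 0.101, RPS2 at -0.24 ± 0.28) did not pass, with 0 adjusted over the list alone in each. The ribosomal list passed on the lower side without control replicate 2 (adjusted p = 0.00630), control replicate 3 (0.000504), treated replicate 2 (0.0107) or treated replicate 3 (0.0478), over a range to 0.890. Of its 24 members 21 were lower, against 18 higher with quantile normalization or the covariate. The oxidative phosphorylation list passed on the higher side without control replicate 1 (adjusted p = 0.00204) and on the lower side without control replicate 2 (0.0277) or control replicate 3 (0.00390), over a range to 0.989. Of its 35 members 21 were lower, against 29 higher with the covariate, 23 after rescaling and 19 with quantile normalization. RPS2 stood at -0.06 without control replicate 1 and UQCRC2 at 0.07 without treated replicate 2.

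Stress lists other than the oxidative stress and NRF2 list did not pass as sets with camera. Heat shock genes had 0 of 12 members past the threshold (camera adjusted p = 0.164). As a set they passed with fry (adjusted p = 0.0454) and with quantile normalization (0.0435, the lowest of a range to 0.592). HSPB8 at 0.88 ± 0.13 and HSPA1A at 0.63 ± 0.16 passed adjusted over the list alone. The osmotic list held SLC6A12 as its 1 rise of 8 (adjusted p = 0.128), and the sodium and proton transport list held SCNN1A as its 1 of 9 (adjusted p = 0.101), each also the only one adjusted over the list alone. Both passed without treated replicate 3 (adjusted p = 0.0478 each) and with a mean of at least 5 FPKM (0.0290 and 0.0404, the lowest of ranges to 0.592). The osmotic list also passed with trimmed-mean factors (adjusted p = 0.0408). Hypoxia genes had 0 of 14 (adjusted p = 0.319), and 4 adjusted over the list alone, of which EGLN3 was higher (0.47 ± 0.12) and ANGPTL4, PDK1 (-0.89 ± 0.23) and BNIP3 lower. Endoplasmic reticulum chaperones (0 of 20, adjusted p = 0.977, HSPA5 at 0.20 ± 0.13, or 0.10 without control replicate 1), ATF4 targets (0 of 19, adjusted p = 0.319, SLC3A2 at -0.83 ± 0.20) and p53 targets (0 of 14, adjusted p = 0.319, CDKN1C at 1.47 ± 0.33) had 0 adjusted over the list alone. CDKN1C was low, with means of 1.27 FPKM in control and 4.17 in treated cells. The set test compares a list with all other genes, whose median log2 fold change was 0.08. Its sign was lower for basal, keratinocyte and chaperone genes although their medians and means were above 0. For ATF4 targets the median (-0.03) and the test were lower and the mean (0.03) higher, and for hypoxia genes the median (0.02) was higher and the mean (-0.09) and the test lower.

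In all, 11 of the 32 lists with at least 5 tested members were shifted, 8 higher and 3 lower, and 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05. One library stood apart from the rest. On the first principal component of the log2 values, which held 61.3% of the variance, control replicate 1 scored 72.8 and the other 5 libraries between -39.6 and 5.43. In lists added after the data were seen, the median log2 fold change between the groups was 0.16 for 31 long mRNAs and -0.12 for 27 short ones, and it turned to -0.15 and 0.15 without control replicate 1. The second component, with 21.0%, had all 3 controls below 0 (-10.5, -17.9 and -31.0) and all 3 treated libraries above it (13.2, 28.3 and 17.9).

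**Figure D3:**
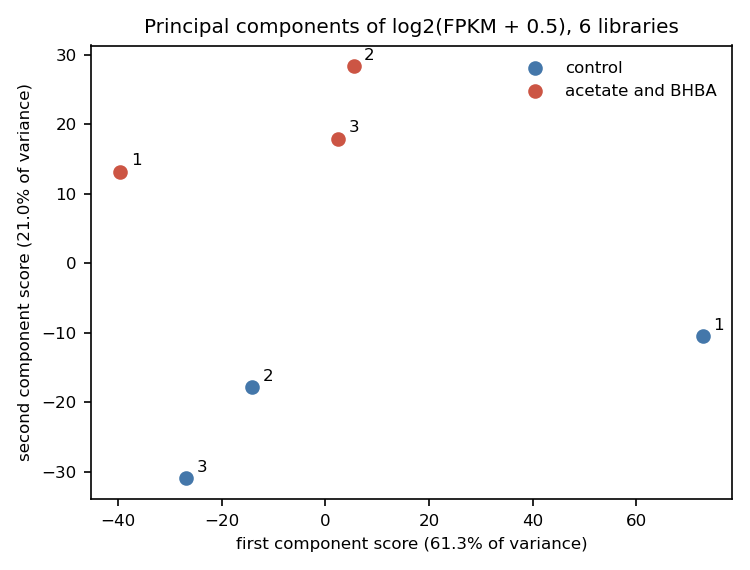
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 0.5), with control libraries in blue, treated libraries in red and replicate numbers beside the points. Control replicate 1 lies at 72.8 on the horizontal axis, and the groups part on the vertical axis.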

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

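The covariate was chosen after the data were seen, and all other alternatives before. The 55 genes kept the sign of their log2 fold change in all 17 alternatives that refit the genes, where tested. The groups did not overlap in any of the 55, so most of these alternatives could not have turned a sign. Only quantile normalization, rescaling, trimmed-mean factors and the covariate could have. The number of genes called was within 1.5 times of the main one with either pseudocount, without a filter, with quantile normalization, with trimmed-mean factors and with either other variance estimate (44 to 69 genes). Of the 55, 38 were among those called with quantile normalization, 39 with trimmed-mean factors, 46 without a filter or without a trend, 44 with the robust estimate, and 53 and 55 with a pseudocount of 0.1 and 1. It was 33 with a mean of at least 5 FPKM, where 8871 genes were tested, 23 after rescaling to a fixed sum, of which 16 were among the 55, and 2089 with the summed FPKM as a covariate, which kept all 55. The genes changed at least 2-fold numbered 30, 23 and 272 under these 3. The cause of the drop after rescaling was not tested. In the covariate fit the median residual SD over genes was 0.11 on the log2 scale, against 0.28 without it, and camera called 9 lists.

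Leaving out 1 library gave 0 to 205 genes, 0 to 149 changed at least 2-fold, and 10 to 13 lists. Without control replicate 1 there were 205, which held all 55, and 10 lists. The fits without control replicate 2 or without any 1 treated replicate gave 0 in limma, with 731 to 921 genes at an unadjusted p under 0.05. The fit without control replicate 3 gave 1, a microRNA gene (bta-mir-2904-3, chosen after its value was seen) that was listed at 0 in control replicate 3 and in all treated libraries. These fits have 1 library fewer, and the self-test did not cover them.

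With the replicate block, limma gave 0 genes, 0 changed at least 2-fold, 584 at an unadjusted p under 0.05, and 11 lists. Libraries with the same number did not deviate together from their group means (correlations -0.73, -0.37 and -0.38), and no control library correlated best with the treated library of its number. These values gave no sign of pairing but cannot exclude it. Deviations within a group are tied to one another, with correlations of -0.77 and -0.87 between control replicate 1 and control replicates 2 and 3.

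Of the lists, 0 passed with an estimated correlation, in place of 11, and the cause was not tested, and 12 passed with fry. Over the single lists and alternatives, 31 calls were lost and 18 gained. The oxidative phosphorylation list turned from lower without a call to higher with one when control replicate 1 was left out (adjusted p = 0.00204, the lowest of a range to 0.444 over the libraries left out and 0.989 over all alternatives), and it was called lower without control replicate 2 or 3. The cause was not tested. Over the named genes and alternatives, 167 calls were lost, 100 gained and 0 turned. Depth is unknown and limits every value near the floor.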

Other observations

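The tests of the covariate and of the share of long transcripts were chosen after the result was seen, as was the demand that a called list hold without each library. The hypotheses on gene lists came from called genes already seen, and their tests were set before the values of those lists were looked at. The other tests were chosen before their results were seen. With the log2 of the summed FPKM as a covariate, camera called 9 of the 11 lists, and lost immediate early genes (adjusted p = 0.104, in a range of 0.00606 to 0.755) and fibroblast markers (adjusted p = 0.160, in a range of 0.00825 to 0.236). Single members passed more often among all genes tested. Of the cholesterol list 19 of 22 members were higher, of the fatty acid synthesis list 8 of 16 were higher, and ACLY (adjusted p = 0.00114), SCD (adjusted p = 0.000909) and FABP3 (adjusted p = 0.000615) were among those past the threshold. Of the interferon list 13 of 18 members were lower, of the cell cycle list 15 of 31 and of the oxidative stress list 12 of 18, against 2 higher. ACACA and FASN did not pass (adjusted p = 0.541 and 0.396). The covariate fit called 2089 genes, 1361 higher and 728 lower, and the highest number in any other split of the 6 libraries was 0. A total of 1 of the 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05.

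Control replicate 1 lay apart from the other 5 libraries, and its summed FPKM was the highest, 1134026. In a list of long mRNAs, such as those of AHNAK and DST, the median log2 deviation of this library from the mean of control replicates 2 and 3 was -0.91 (95% bootstrap interval -1.07 to -0.86, 29 of 31 genes lower). In a list of short mRNAs it was 0.85 (0.82 to 1.01, 26 of 27 higher). Both intervals come from resampling the genes of a list, with the libraries held fixed. After quantile normalization gave every library the same distribution, the first component still held 53.4% of the variance, from 61.3%. Library scores were not taken after it, so this does not show whether control replicate 1 still stood apart. The top 20 genes held 20.9% of its summed FPKM, against 17.8% to 19.0% in the other libraries. A few abundant genes taking more of the reads would lower all other genes alike. The opposite shifts of the long (-0.91) and short (0.85) mRNAs argue against that as the only account for these genes. Whether it had a smaller part stays open. In the lists of long and short mRNAs, control replicate 1 was shifted toward short transcripts. Whether that shift came from RNA fragmentation, size selection or the length model behind FPKM stays open. No biological explanation was tested for a single library.

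All 55 genes called between the groups stayed past the threshold in the same direction with the summed FPKM as a covariate. Their log2 fold changes were 0.946 to 1.06 times those without it. Genes pass the main test only with a small spread within groups, so their values follow the summed FPKM little to begin with. That outcome was therefore likely beforehand and does not settle whether the trend along the summed FPKM had a part. A total of 1 of the 10 splits of the 6 libraries, the real one, gave 55 genes or 50 genes changed at least 2-fold, and the highest other split gave 0 of each. For the lists it was also 1 of 10, with 11 lists in the real split and up to 8 in another, and 10 splits are too few for a share under 0.05. In this way camera at its preset correlation called lists in splits that cross the groups. The split with control replicate 1 and treated replicates 2 and 3 on one side gave 3807 genes at an unadjusted p under 0.05, against 1282 in the real one, which points to the structure of the first component, and effects of the treatment may still be mixed with differences between cultures that the labels do not give.

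A set of hypotheses was tested on lists of genes whose values had not been looked at, 3 lists in all. Each interval given here is a 95% bootstrap interval over the genes of a list, with the libraries held fixed. It leaves out the spread between libraries and so does not measure the uncertainty of a treatment effect. PER1 (log2 fold change 1.34 ± 0.12, adjusted p = 0.0220), TSC22D3 and SCNN1A, all known to respond to glucocorticoids, rose, so other glucocorticoid receptor targets may have risen too. Of 11 such genes 9 were higher, with a median log2 fold change of 0.45 (interval 0.31 to 0.53) and 0 past the threshold, and camera gave p = 0.0356, or 0.107 adjusted over the 3 lists, 0.438 with an estimated correlation and 0.485 without control replicate 1, so the question stays open. Genes better known from neurons (EEF1A2, ACHE, SYNGR3, PIANP and NAP1L5) rose beside the linker histone gene H1F0, and ketone bodies have been described as histone deacetylase inhibitors, so genes that such inhibitors induce might have risen. Of 13 of them 7 were higher, with a median of 0.09 (interval -0.11 to 0.35). The camera test in limma gave 0.690 both as p and adjusted over the 3 lists, which neither shows such a rise nor bounds it closely. DHRS3, which retinoic acid induces, fell, so other retinoic acid targets might have fallen. Of 10 of them 7 were lower, with a median of -0.12 (interval -0.44 to 0.12). The camera test in limma gave 0.0961, or 0.144 adjusted over all lists of this kind. Its unadjusted p was 0.157 with an estimated correlation, 0.524 without control replicate 1 and 0.0492 with the summed FPKM as a covariate. These values leave the fall of retinoic acid targets open as well. PER1, H1F0 and SYNGR3 were chosen after their values were seen.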
